A study of Escherichia coli with 36 samples.

How the data were processed

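H-NS, a nucleoid protein that silences AT-rich genes, and the beta subunit of RNA polymerase (RNAP) were mapped in Escherichia coli K-12 by chromatin immunoprecipitation and sequencing (ChIP-seq). The cells, an MG1655 derivative, grew in MOPS minimal medium with 0.2% glucose and received rifampicin at 100 µg/mL, which blocks the start of transcription, or its methanol solvent. A second assay, Nitro-seq, mixed purified protein with purified MG1655 genomic DNA and sequenced the DNA that the protein held on a nitrocellulose filter of 0.45 µm pore size. Of the 36 samples, 20 had a peak list and were used: 8 ChIP-seq libraries in 4 groups of 2 and 12 Nitro-seq libraries in 4 groups of 3. The Nitro-seq groups held H-NS at 100 nM, Hha and H-NS at 100 nM each, StpA at 50 nM and Fis at 12 nM. The other 16 samples, which include inputs, reactions without protein and other protein concentrations, were not analysed here. The labels do not say whether replicates came from separate cultures or protein preparations, so the exact p-values between groups measure the spread between these libraries, which may be technical. The rotation and gene-order tests described further on compare places on the chromosome and measure no spread between libraries.

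Per the submitters' processing notes, the tools included Trimmomatic 0.38, FastQC, Bowtie2 2.3.4.2, SAMtools 1.9 and bedtools 2.8. Peaks were called with MOSAiCS, per the file headers, and there is 1 list for each library. Each deposited list gives start, end and a score on sequence NC_000913.3. In every list at least 99.5% of the scores, multiplied by the number of 200 bp bins in the peak, came within 0.01 of a whole number, so the deposited score is read here as the authors' mean tag number per bin, with no scaling between libraries. It was used to rank and filter peaks within a list and for medians by chromosome position within a list. The named gene ends were ranked by its mean over the 2 libraries of a group, which are not scaled to each other, so the library with higher scores weighs more there. Library depth is unknown from these lists, so a longer or shorter list can reflect depth as well as binding. All peak ends of the RNAP lists lay on the 200 bp bin borders or chromosome ends, whereas most peaks of the other groups had been trimmed, so RNAP positions are resolved to about 200 bp.

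Gene positions came from the NCBI RefSeq table of assembly ASM584v2, which carries the same sequence and has 4651 genes. That table holds neither strand nor sequence. GC content and sequence motifs under peaks were therefore not analysed here. The planned window at gene starts, from 150 bp outside to 50 bp inside, was placed at both ends of every gene, 9302 ends in all, and covers 28.1% of the chromosome. The lists have no summit, so the midpoint of a peak was taken as its position. Of the 850 genes asked for in 19 gene lists fixed before the data were examined, 844 matched.

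A gene was called when the share of its length under peaks was higher in every library of 1 group than in every library of the other by at least 0.5. A gene end was called when every library of 1 group had a peak position in its window and no library of the other had a position within 300 bp. Values per library were compared with an exact two-sided permutation test. With 2 against 2 libraries this test cannot give a p below 0.333, and with 3 against 3 not below 0.1, so neither can pass 0.05. Without a margin, chance alone would separate the libraries of 2 groups completely in 33.3% of genes with 2 against 2 libraries and in 10% with 3 against 3. Regions under peaks in every replicate of a group, called shared regions here, were compared with other groups and with gene lists by a one-sided rotation (permutation) test. The regions were turned as a block around the circular chromosome in 1 kb steps, 4642 positions with the real one, so the smallest p it can give is 0.000215. Benjamini-Hochberg adjustment covered the 28 pairs of groups, and separately the 152 pairs of gene list and group. The smallest adjusted p was 0.000274 for pairs of groups, 0.00205 for lists above and 0.00655 for lists below the rotated value, each set by the smallest p that the rotations can give. A test of gene lists among called genes, in which the calls were turned around the gene order, was added after the data were examined and adjusted over 228 pairs of list and direction, with 0.00817 as its smallest adjusted p. In it, 8 pairs passed for more calls than when turned and 2 for fewer. The turned calls were not matched for gene length, and a short gene can be called under a single peak. Lists of short genes, such as small and transfer RNA genes, may hold more calls for that reason. RNAP calls by gene length and StpA lists without replicate 1 were also added then.

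Genes named in the text were chosen by a rule fixed beforehand: 16 fixed genes, the longest runs of called neighbours, the called ends with the highest peak scores (ends reached by the same peak counted once), and up to 4 called members of each list. Exceptions are marked. Ribosomal RNA genes and insertion sequences exist in several copies, so their calls are uncertain. On simulated peak lists with 200 changed genes among 4651, the gene rule recovered 90% for H-NS ChIP, 91.5% for RNAP ChIP and 83% for Nitro-seq, with at most 1 false call per direction. The simulated libraries were copies of a single real list with small shifts of peak ends and few peaks dropped. They do not carry the larger differences seen between some real replicates, so the false call number holds for that setting only. Each planted change spanned a gene without cover from end to end, with small shifts, so the recovered percentages hold for such changes only. Of 200 random lists of 30 genes, 2% had a rotation p below 0.05. The genes of these lists were scattered over the chromosome, whereas several tested lists are operons or clusters. The rate of false passes for clustered lists was not measured.

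Replicate numbers are shared between groups. For Hha plus H-NS against H-NS alone, same-numbered libraries deviated together across genes (correlations 0.331, 0.172 and 0.128), so these libraries were taken as paired, from the data and not from the labels. By shared over joint length under peaks, H-NS replicates 1 and 2 were nearest to their own number (0.844 and 0.866). H-NS replicate 3 was nearer to replicate 2 of Hha plus H-NS (0.867) than to its replicate 3 (0.803). The alternatives tried were a replicate block, each replicate left out, the upper part of each list by score, joined peaks, other margins and windows, and regions under a peak in any replicate. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.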

Results

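Peak lists were compared for H-NS and RNAP in cells with and without rifampicin, with 2 libraries per group, and for H-NS, Hha plus H-NS, StpA and Fis on bare genomic DNA, with 3 libraries per group. H-NS peaks in solvent-treated cells covered 636 kb ± 19.3 (SD, n = 2) of the chromosome and RNAP peaks 479 kb ± 6.08 (SD, n = 2). In vitro, H-NS peaks covered 857 kb ± 63.2 (SD, n = 3). The Jaccard index between replicates, the shared over the joint length, was 0.931 for H-NS in solvent and 0.740 for RNAP in solvent. It averaged 0.860 for H-NS in vitro, 0.780 for Hha plus H-NS, 0.734 for Fis and 0.651 for StpA. StpA replicate 1 stood apart, with 310 peaks against 604 and 603 in replicates 2 and 3.

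**Figure D1:**
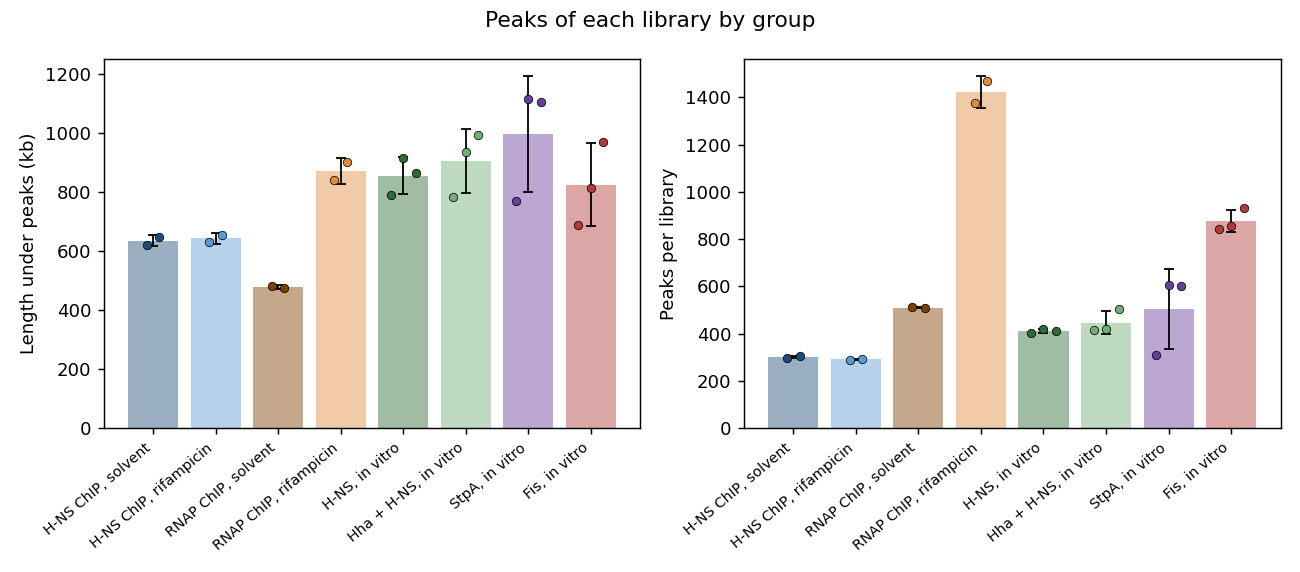
Length under peaks in kb (left) and number of peaks (right) for each library, with bars at the group mean, error bars of 1 SD and a point per library. The RNAP lists with rifampicin hold 1376 and 1470 peaks, against 511 and 508 with solvent.

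H-NS covered the listed lipopolysaccharide genes and many genes of fimbriae and silenced operons in solvent-treated cells. The list for the lipopolysaccharide core and O antigen, which build the outer part of the cell surface, held 22 genes. All 22 had at least 50% of their length under peaks in both libraries. So did 36 of 59 genes for type 1 and cryptic fimbriae and 17 of 31 genes in a list of H-NS-silenced operons. The lipopolysaccharide list leaves out waaF and waaA, beside the same cluster, which lay under no solvent H-NS peak. The bgl operon regulator bglG, the curli regulator csgD and waaQ of the lipopolysaccharide core were each covered over 100% ± 0 (SD, n = 2) of their length. The share was 77.5% ± 2.59 (SD, n = 2) for proV, a subunit of an osmoprotectant transporter. Shared H-NS regions held 95.7% of the lipopolysaccharide list, against 13.2% when rotated (rotation permutation test, adjusted p = 0.00205). Genes of amino acid biosynthesis had 0.357% of their length in these regions, against 13.2% when rotated (rotation permutation test, adjusted p = 0.00655). The longest shared region ran from 1207800 to 1223428 on NC_000913.3 and touched 24 genes, among them bluR and ycgZ (chosen after their values were seen).

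The next comparison asked whether H-NS occupancy is altered when transcription is stopped. With rifampicin H-NS covered 644 kb ± 17.0 (SD, n = 2), a difference of 7.90 kb that was smaller than the spread between replicates (exact permutation p = 0.667). It was -5.74 kb without solvent replicate 1, 21.5 kb without solvent replicate 2, 19.9 kb without rifampicin replicate 1 and -4.15 kb without rifampicin replicate 2. Shared regions of the 2 treatments had a Jaccard index of 0.880. Single libraries of different treatment had 0.859 to 0.870, against 0.873 between the rifampicin replicates and 0.931 between the solvent replicates. By the margin rule 16 genes were gained and 15 lost. The gained genes included lacA and lacY of lactose uptake and use, the curli gene csgC with its neighbour ymdA, and the iron-responsive small RNA ryhB with its neighbour yhhY. lacA went from 0% to 100% ± 0 (SD, n = 2), and gatC of galactitol uptake, annotated as a pseudogene, from 6.85% ± 4.06 to 100% ± 0 (SD, n = 2 each). The lost genes included pqqL with yddB, ycaN with ycaK, and yabP with yabQ. pqqL fell from 100% ± 0 to 25.0% ± 24.9 (SD, n = 2 each). No gene list passed among these calls. Leaving out a library can only add calls under this rule, and gained genes then numbered 28 without solvent replicate 2, 40 without rifampicin replicate 1 and 38 without rifampicin replicate 2, and lost genes 27 without solvent replicate 1, 28 without rifampicin replicate 1 and 26 without rifampicin replicate 2. The other ways to split the 4 libraries called at most 7 genes in both directions together, against 31.

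RNAP in solvent-treated cells lay on the genes of the translation apparatus. All 22 ribosomal RNA genes, 85 of 86 transfer RNA genes and 46 of 54 ribosomal protein genes had at least 50% of their length under peaks in both libraries, each list above its rotated value of about 8.76% to 8.78% of length (rotation permutation test, adjusted p = 0.00205). With rifampicin the numbers were 1 of 22, 44 of 86 and 15 of 54. rpsA, which encodes ribosomal protein S1, was covered over 100% ± 0 of its length with solvent and 16.4% ± 0 with rifampicin (SD, n = 2 each). Of the 22 genes for ATP synthase and NADH dehydrogenase I, 11 were covered with solvent, a list that did not pass (rotation permutation test, adjusted p = 0.0748), and 3 with rifampicin. For small RNA genes the order was the opposite, with 41 of 107 covered with solvent and 72 with rifampicin, as it was over all 4651 genes, with 510 and 793.

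RNAP peaks were 2.79 times as many with rifampicin, at 1423 ± 66.5 against 509.5 ± 2.12 per library (SD, n = 2 each, exact permutation p = 0.333, the smallest possible). By gene length, 209 genes lost RNAP. They included a run of 9 genes that starts with glmS, glmU and the ATP synthase genes atpC and atpD, a run of 6 that starts with gatD, gatC, gatB and gatA of galactitol use, and the ribosomal protein run of rplO, rpmD, rpsE and rplR. Runs in the rRNA operons, such as rrsC and rrlC, were also called, with uncertain copies. Among the lists, 29 of 54 ribosomal protein genes, 39 of 86 transfer RNA genes and 18 of 22 ribosomal RNA genes were lost (gene-order permutation test, adjusted p = 0.00817 each). RNAP was gained on 454 genes. Among them were 28 of 107 small RNA genes, with cpxQ and flgO as examples (gene-order permutation test, adjusted p = 0.00817). The 35 of 194 cryptic prophage genes, such as relB and yagJ, did not pass (gene-order permutation test, adjusted p = 0.091). Rifampicin RNAP peaks had a median width of 600 bp, so short genes such as those for small RNAs can be called under a single peak. The gene-order test was not matched for gene length. The other splits of the 4 libraries called at most 4 genes, against 663. With a margin of 0.25 the gained count was 885, and with 0.75 it was 260.

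Positions of RNAP peaks were at gene ends in 58.5% ± 1.70 of solvent and 63.9% ± 0.850 of rifampicin peaks (SD, n = 2 each, exact permutation p = 0.333), both above 28.1% or 28.2% when rotated (rotation permutation test, p = 0.000215 in each library). This difference of 5.45 percentage points depended on the window, at 0.512 with 50 bp on either side and -0.778 with 300 bp outside and 100 bp inside, and was 11.6 with stricter peaks. Positions between genes made up 29.9% ± 0.847 with solvent and 44.4% ± 2.22 with rifampicin (SD, n = 2 each, exact permutation p = 0.333), a measure added after the data were examined. RNAP positions appeared at 852 gene ends of 821 genes and disappeared from 80 ends of 76 genes. The highest-scored new ends were those of ftsX, ftsZ, tff, yidQ, fdhD, mzrA, hemC, yfdY, yhfA and talA. Without strand, such an end need not be the start of the gene named, and a peak there may belong to a neighbour. The peak at the ftsX end, for example, also touched rpoH. Of the gained ends 762 lay under no solvent peak, but those of ftsX, tff, fdhD, ftsZ and yhfA already lay under a solvent peak with another midpoint. The highest-scored lost ends belonged mostly to transfer RNA genes, namely leuT, glyV, leuU, argV, glyU, leuX, glnW and metV, together with the cold shock gene cspA and the magnesium transporter gene mgtA. Of the lost ends, 35 lay under no rifampicin peak, so at the others, those of cspA, glyV, argV, glyU and leuX among them, a peak with another midpoint remained in at least 1 rifampicin library. Without solvent replicate 1 the lost count was 138 and without replicate 2 it was 161. With the 50 bp window 339 ends were gained and 42 lost, and with the 300 bp window 1422 and 192.

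RNAP and H-NS regions overlapped less than when rotated with solvent and more than when rotated with rifampicin. They had 24.4 kb in common with solvent, 0.454 times the rotated value (rotation permutation test for less overlap, adjusted p = 0.00603). With rifampicin in both, 125 kb were in common, 1.19 times the rotated value (rotation permutation test for more overlap, adjusted p = 0.0021). RNAP positions inside H-NS regions of the same treatment made up 9.42% ± 0.872 of solvent and 15.3% ± 0.915 of rifampicin peaks (SD, n = 2 each, exact permutation p = 0.333). The 95% Wilson intervals of the libraries were 6.65% to 11.6% and 7.72% to 13.0% with solvent, and 14.1% to 18.0% and 13.0% to 16.6% with rifampicin, and they cover counting error only. The solvent libraries lay below the rotated 13.2% (one-sided rotation permutation test, unadjusted p = 0.00215 and 0.0179) and the rifampicin libraries above the rotated 12.9% (p = 0.000215 and 0.00905 by the same permutation test). Among as many top-scored rifampicin peaks as there were solvent peaks, the share was 9.71%.

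**Figure D2:**
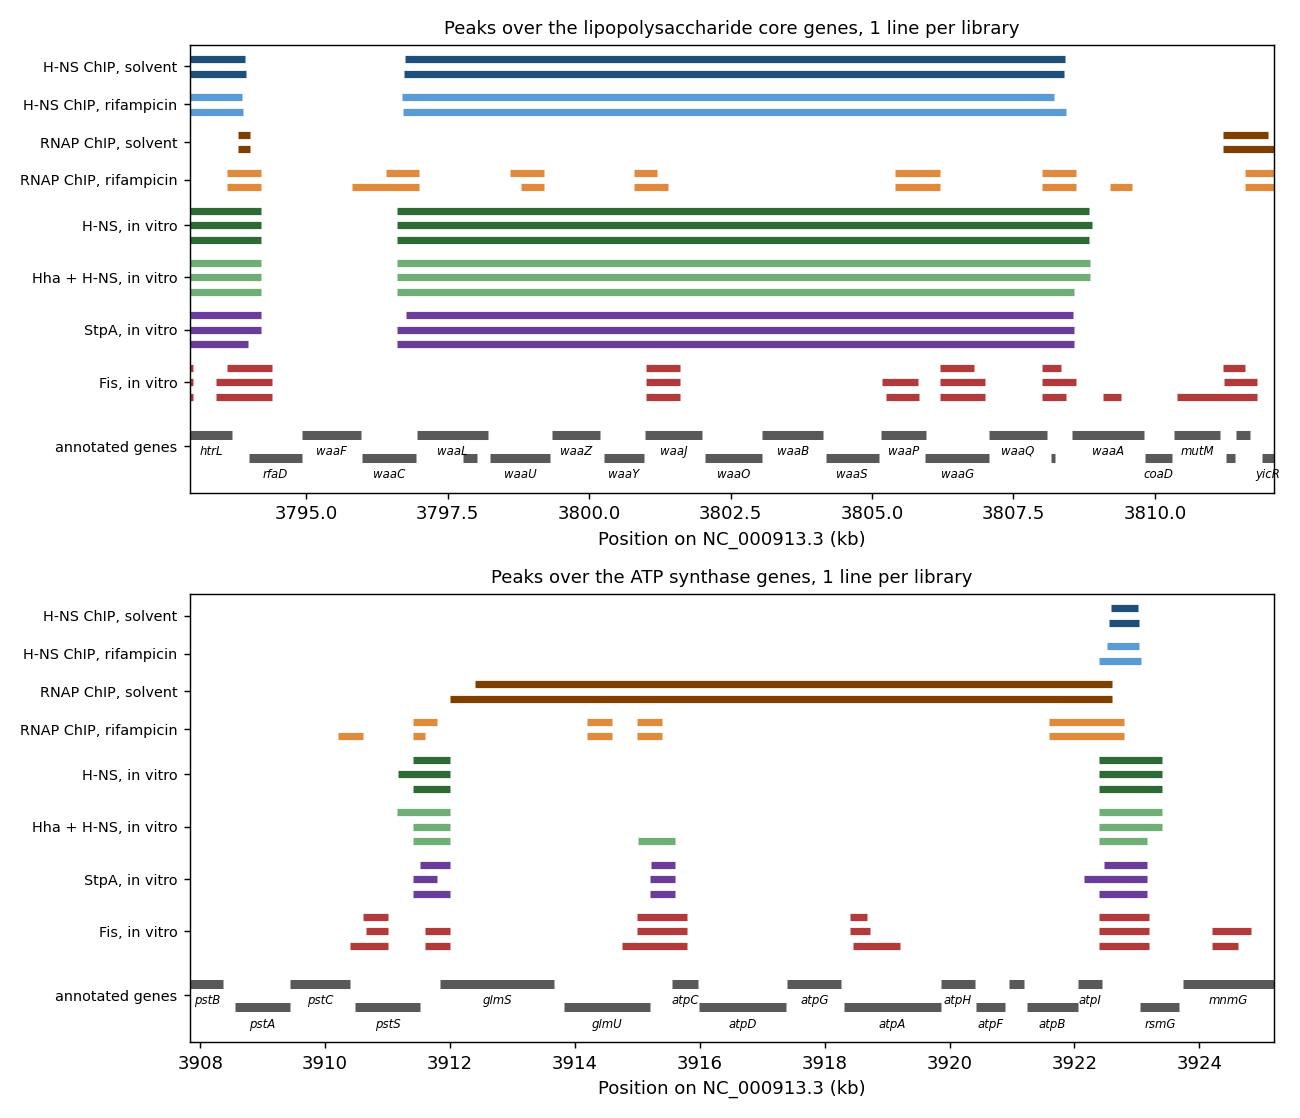
Peaks of every library, 1 line each and coloured by group, over the lipopolysaccharide core genes (top) and the ATP synthase genes (bottom), with annotated genes in grey and the position on NC_000913.3 in kb on the x axis. A long H-NS peak over the genes from waaL to waaQ appears in all H-NS libraries. The shared regions were 3796739 to 3808401 in cells with solvent and 3796713 to 3808226 with rifampicin. The single RNAP peak over the ATP synthase genes with solvent, 3912400 to 3922599 in replicate 1, gives way to shorter separate peaks with rifampicin.

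Purified H-NS on bare DNA was set against H-NS in solvent-treated cells to ask which sites need nothing but protein and DNA. Shared regions overlapped with a Jaccard index of 0.610, 5.18 times the rotated length (rotation permutation test, adjusted p = 0.000274), and in vitro regions held 85.0% of the length found in cells. Of the lipopolysaccharide genes 21 of 22 were covered in vitro, and of the fimbrial genes 38 of 59. The margin rule called 211 genes bound in vitro and not in cells. These included the run of dgcP, yoaK, yoaJ and yeaQ, the prophage genes yfdR, yfdS and yfdT, the run of yieH, cbrB, cbrC and yieK, and spf, yihA and csrC, where spf and csrC encode small RNAs. Small RNA genes made up 13 of them, out of 107 (gene-order permutation test, adjusted p = 0.042, not matched for gene length). The heat shock genes ibpA and ibpB went from 0% in cells to 100% ± 0 in vitro (SD, n = 3). In the other direction 53 genes were bound in cells only, among them xylA and xylB of xylose use, ompG with ycjW, kduD with kduI, and cnu, which encodes a small partner of H-NS. Other splits of the 5 libraries called at most 44 genes, against 264. These groups differ in assay and in the material used, so the calls do not separate the cell from the assay. The in vitro lists also had more of their length near the replication origin than the solvent lists. Of the in vitro peaks over the 211 genes 63.5% scored below their library's median.

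Hha, a small protein that binds H-NS, was added at equal concentration. The libraries with Hha covered 905 kb ± 109 (SD, n = 3), 47.9 kb more than H-NS alone (exact permutation p = 0.6), and shared regions had a Jaccard index of 0.856. That difference was 14.6 kb without H-NS replicate 1, 77.6 kb without H-NS replicate 2, and 108 kb without replicate 1 of Hha plus H-NS. It was 3.13 kb without replicate 3 of Hha plus H-NS. With Hha, 5 genes were gained, namely ybgV, ybgU, osmB, yciH and ykiE, and 0 lost. osmB, an osmotically induced lipoprotein gene, went from 0% to 100% ± 0 (SD, n = 3). Other splits of the 6 libraries called up to 12 genes, while the 3 other splits that part every numbered pair called 0, 0 and 2. Since the pairs were read from these same libraries, that smaller set of splits does not show that 5 is high. With the pairs kept, the exact permutation p of the covered length was 0.5. The gained count was 12 without H-NS replicate 2 and 30 without Hha plus H-NS replicate 1. The lost count was 1 without H-NS replicate 1 or 2, 4 without Hha plus H-NS replicate 1, 3 without its replicate 2 and 1 without its replicate 3.

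StpA, a paralogue of H-NS, was used at 50 nM against 100 nM for H-NS, so protein and concentration differ together. Of the lipopolysaccharide genes 21 of 22 were covered in all 3 StpA libraries, and of the fimbrial genes 30 of 59, against 21 and 38 in all 3 H-NS libraries. In StpA replicates 2 and 3 alone the numbers were 22 and 45. A count over fewer libraries can only stay or rise, so these counts do not settle the order for fimbrial genes. The lists were not tested for a difference between the proteins. Shared StpA and H-NS regions had a Jaccard index of 0.632. StpA peaks covered 998 kb ± 197 (SD, n = 3), 141 kb more than H-NS (exact permutation p = 0.4). The difference was 254 kb without StpA replicate 1, 81.6 kb without replicate 2 and 85.9 kb without replicate 3. Bound with StpA and not with H-NS were 43 genes, including the CRISPR Cascade genes casC, casD and casE, the prophage genes yfjM, rnlA and rnlB, and elaA with rbn. casD went from 0% to 100% ± 0 (SD, n = 3 each). The 3 called Cascade genes of 8 did not pass (gene-order permutation test, adjusted p = 0.0637). yaaW, speD, osmY and ytjA were bound with H-NS and not with StpA. StpA replicate 1 had few peaks far from the replication origin, and without it the counts were 188 gained and 8 lost, while without H-NS replicate 1 the lost count was 13. Of the 188 genes, 90 were also bound in replicate 3 of Hha plus H-NS, 30 in its replicate 2 and 7 in its replicate 1, while 43 were bound in StpA replicate 1 and 43, 53 and 60 in the Fis replicates 1, 2 and 3. That replicate 3 had a Jaccard index of 0.837 and 0.838 with StpA replicates 2 and 3, against 0.722 and 0.837 with replicates 1 and 2 of its own group. In StpA replicates 2 and 3 together, 6 of 7 curli genes were covered, against 0 of 7 in all 3 libraries. For prophage genes it was 93 of 194, against 41. The rotation permutation test over the lists of these 2 libraries gave adjusted p = 0.141 for curli and 0.0139 for prophages. These counts, too, can only stay or rise with fewer libraries. The flagellar regulator gene flhD was covered over 59.5% ± 52.7 (SD, n = 3), with no cover in replicate 1, and over 0% in H-NS libraries.

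Fis, a nucleoid protein that activates stable RNA promoters, gave another map. It was used at 12 nM against 100 nM for H-NS, so protein and concentration differ together. Its peaks were 2.14 times as many as those of H-NS, at 877 ± 47.4 per library against 410 ± 7.51, and narrower, with a median width of 784 bp ± 130 against 1486 bp ± 100 (SD, n = 3 each, exact permutation p = 0.1, the smallest possible, for both). Fis peaks covered 826 kb ± 141 (SD, n = 3), a difference of -30.9 kb from H-NS (exact permutation p = 0.9). That difference was 36.7 kb without Fis replicate 1 and -104 kb without Fis replicate 3. It was -64.2 kb without H-NS replicate 1 and -1.30 kb without H-NS replicate 2. Bound with Fis and not with H-NS were 352 genes, among them 31 of 86 transfer RNA genes with alaW, alaX, argV and argX as examples (gene-order permutation test, adjusted p = 0.00817). Of the 22 ribosomal RNA genes 0 were called, and rrsA was covered by Fis over 0% ± 0 (SD, n = 3). The rule counts only cover of the gene itself, so Fis peaks beside these genes are not seen by it. Narrow peaks also reach the margin more easily on short genes, such as those for transfer RNA. Runs included metU, glnW, glnU and leuW, the run of tyrV, tyrT, purU and ychJ, and murA with ibaG and mlaB of the cell envelope. Bound with H-NS and not with Fis were 470 genes. They included 24 of 59 fimbrial genes such as fimA and elfA (gene-order permutation test, adjusted p = 0.00817) and 13 of 22 lipopolysaccharide genes such as waaL and waaO (gene-order permutation test, adjusted p = 0.0429). The longest run held 11 such genes and starts with mcrA, icdC, iraM and ymgK. Shared Fis regions overlapped RNAP regions of solvent-treated cells 1.74 times as much as when rotated and those of H-NS in vitro 2.02 times (rotation permutation test, adjusted p = 0.000274 each).

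**Figure D3:**
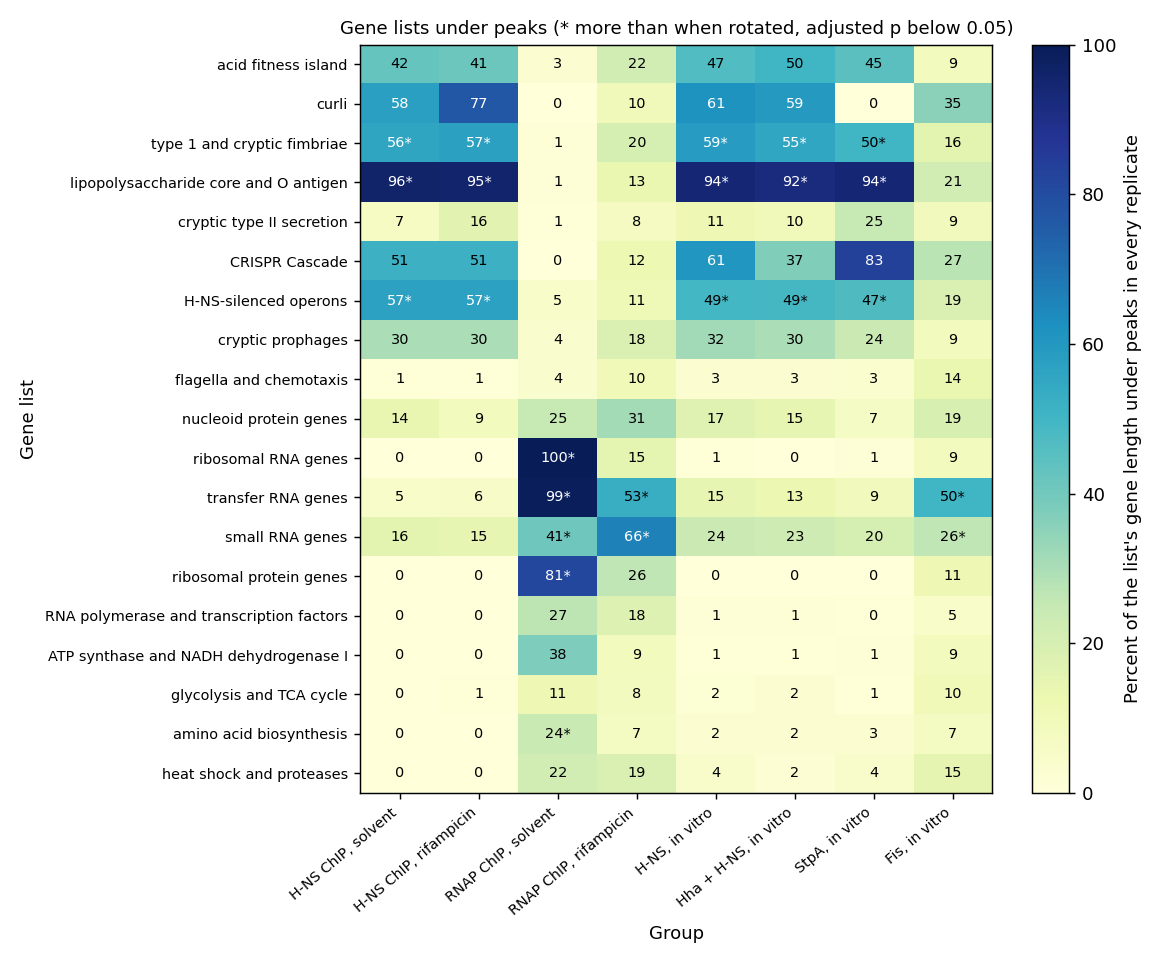
Percent of each gene list's length, on the colour scale, that lay under peaks in every replicate of a group, for 19 gene lists (rows) and 8 groups (columns). Asterisks mark values above the rotated ones after adjustment over 152 tests, 24 in all, and the StpA column includes replicate 1, which has few peaks far from the origin.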

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

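The tests of RNAP by gene length, of ends under no peak of the other treatment, of positions between genes and of StpA lists without replicate 1 were chosen after the data were examined. Library depth is unknown and limits every count of peaks. GC content and motif results and their alternatives were not run, since no genome sequence was used here. The RNAP peak number and the RNAP share in H-NS regions kept their direction under the alternatives tried. The peak number difference was 457 with stricter peaks, which follows from keeping the same part of every list. The covered length differences stayed positive but ranged from 3.13 to 108 kb for Hha plus H-NS and from 81.6 to 254 kb for StpA. The H-NS covered length difference turned negative without solvent replicate 1 or rifampicin replicate 2, with a range of -5.74 to 21.5 kb. The Fis covered length difference ranged from -104 to 36.7 kb and turned positive without Fis replicate 1. The RNAP share at gene ends was -0.778 percentage points with the 300 bp window. The Jaccard index of H-NS in vitro and in cells passed under every alternative, from 0.474 with stricter peaks to 0.621 with a replicate left out. The cause of these changes was not tested.

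With a margin of 0.25, calls were 26 for H-NS gained, 885 for RNAP gained, 8 for Hha, 65 for StpA and 620 for Fis gained, and 80 for H-NS in cells only. With 0.75 they were 9, 260, 25 for StpA gained, 1 for StpA lost, 220 for Fis gained and 33 for H-NS in cells only. With any overlap they were 32 and 28 for H-NS gained and lost, 11 and 1 for Hha gained and lost, 88 for StpA gained, 839 for Fis gained and 405 for H-NS in vitro only. With stricter peaks they were 2 and 1 for Hha gained and lost, 2 for StpA lost, 196 and 296 for Fis gained and lost, and 494 RNAP ends gained. The narrow window gave 339 ends gained and 42 lost, the wide window 1422 and 192, and ends under no rifampicin peak were 35. With each replicate left out, calls ranged from 19 to 40 for H-NS gained, 17 to 28 for H-NS lost, 85 to 161 for RNAP ends lost, 5 to 30 and 0 to 4 for Hha gained and lost, and 45 to 188 and 4 to 13 for StpA gained and lost. Of the 24 list and group pairs above the rotated value, 24 held with regions in any replicate and with peaks placed at random. Pairs below the rotated value were 6, and 19 with regions in any replicate. With peaks placed at random, 5 of these 6 held. Leaving out a library, the 0.25 margin and the replicate block can only keep or add calls, so they say nothing of how stable a named gene is. The checks covered only genes named through runs of called neighbours or the highest-scored ends. Among alternatives that can remove a call, these lost it in 68 of 197 checks with stricter peaks and 48 of 177 with the 0.75 margin. They lost it in 10 of 20 with the narrow window and 10 of 20 with only ends under no peak of the other treatment. With joined peaks, 0 of 129 lost it.

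The replicate block moved no count of calls by over 1.5 times: RNAP gained 455 genes, Fis 353 and lost 473 with it. For H-NS and RNAP ChIP, the paired deviations correlated at 0.135 and -0.043, and for StpA and Fis not every sample correlated best with its own number in both comparisons.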

Other observations

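The tests of genes called for StpA replicate 1 alone, of distance from the replication origin and of H-NS leaving RNAP sites were chosen after their results were seen. Peak scores differed with position along the chromosome in most lists. With the chromosome in 4 parts by distance from the origin, the nearest part had a median score of 6787 in H-NS ChIP solvent replicate 1, against 3770 in the farthest, and the other H-NS ChIP and solvent RNAP libraries had the same order. The rifampicin RNAP libraries had no steady order over the 4 parts. In the 12 Nitro-seq libraries the order was the opposite, with 2877 in the nearest and 4229 in the farthest part in H-NS replicate 1. Scores are not scaled between libraries, so this compares positions within a list. The hns gene itself, at 1292509 to 1292922, was covered by in vitro H-NS over 100% ± 0 (SD, n = 3) and by solvent RNAP over 100% ± 0 (SD, n = 2). In cells H-NS covered it over 100% ± 0 with solvent and 50% ± 70.7 with rifampicin (SD, n = 2 each), with 1 rifampicin library at 0%, and StpA covered it over 66.7% ± 57.7 (SD, n = 3). stpA and hha were covered over 100% by H-NS in every library in cells and in vitro, whereas fis was at 0% in every group.

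StpA replicate 1 had a mean Jaccard index of 0.524 with its fellow replicates, which reached 0.907 with each other. For a stricter call of the same sites, 97.1% of its peaks overlapped peaks of both other lists, which met the bound set beforehand in favour of it. A test added later argued against it. By the margin of 0.5, 102 genes were called for replicate 1 against both others, and 21 and 37 for replicates 2 and 3. Genes called this way may be partly covered in the other replicates. Length under peaks of replicate 1 near the origin was 2.19 times that far from it, against 0.833 to 1.36 in the other 19 libraries. A call that follows distance from the origin is thus a candidate explanation. Another protein's library cannot be told apart from this, since its mean index with in vitro H-NS was 0.563 over the chromosome, while near the origin the highest index with another group was 0.683 and that with its own group 0.678. No biological explanation was tested.

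The 211 genes bound by H-NS in vitro and not in cells had 5.52% of their length under H-NS ChIP peaks with solvent and 13.4% with rifampicin. This rise of 7.87 percentage points does not decide whether transcription keeps H-NS off these genes, since they were chosen for low cover in the same solvent libraries and some rise would come from that choice alone. Weaker sites may also account for part of the pattern, since 63.5% of the in vitro peaks over these genes scored below their library's median. Scores in the in vitro H-NS lists were also lower near the replication origin. In replicate 1 the median was 2877 in the nearest part and 4229 in the farthest. A low score may therefore reflect position, and the 2 were not separated. Broader in vitro peaks stay open too, as 56.4% of the genes lay under in vitro peaks that also held DNA bound in cells. These values exclude none of the 3 explanations. Position along the chromosome differed as well. Near the replication origin, H-NS covered 453 to 516 kb in the in vitro libraries, against 289 and 300 kb in the solvent ChIP libraries. Far from it, the values were 337 to 400 kb against 333 and 350 kb. Most of the extra length in vitro thus lay near the origin, and whether this accounts for calls among the 211 genes was not tested.

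The larger share of RNAP positions in H-NS regions with rifampicin may come from the larger number of peaks in those lists, which adds peaks of lower rank. Among as many top-scored rifampicin peaks as the solvent lists held, 9.71% lay in H-NS regions, under the higher of the solvent values. New RNAP peaks of lower rank inside H-NS regions would give the same value, so it does not decide between these. Scores are not scaled between lists, so these values do not show that the rifampicin peaks are weaker. That H-NS leaves the places where RNAP appears was not decided, since 87.4% of the rifampicin positions in solvent H-NS regions also lay in rifampicin H-NS regions. A biological effect of the drug on where RNAP sits was not tested apart from these.

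Other splits of the 6 libraries are too few for a share under 0.05. For Hha plus H-NS against H-NS, 4 of 10 splits called as many genes, with 5 in the real split and 12 in the highest other, and among the splits that part every numbered pair the highest other was 2. The pairs were read from the same libraries, so this smaller set decides nothing. For StpA the real split called 47 genes and the highest other 13, with 1 of 10 as large. For Fis these were 822 and 2, with 1 of 10 as large.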
